A study of Danio rerio with 16 samples.

How the data were processed

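Total RNA of 16 single male zebrafish brains, 4 per dose, was labelled with Cy3 and hybridised to Agilent one-colour arrays, per the labels' protocols. The scanner files hold 1 array each; values came from Agilent Feature Extraction 12.0, per the submitters' processing notes (12.0.3.1 per the file headers). The intensity used here is the processed signal, which the software had background-subtracted and detrended within each array, per the file headers, and which was deposited without normalization between arrays; median spot and median local background intensity were deposited beside it, as were other values, flags of 0 or 1 for spots that are outliers, saturated or well above background, per the file headers. The authors' deposited matrix of processed intensity equals the processed signal of the same spots on every array (100% of values), on a linear, uncentred scale, with column medians from 83.4 to 212, so it was not run as a separate setting. The authors also deposited a list of changed probes for each dose with the fold change as a ratio, a signed fold score and its log2 value; the test, threshold and normalization behind these lists are not given in the sources used here.

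Each array had 180880 spots, of which 4854 were controls, and 128291 probes. Control spots and outlier-flagged spots were left out, log2 signals were taken relative to the 75th percentile of the array, and spots of a probe were averaged. Probes were kept where well above background on all arrays of at least 1 group (110542, or 86.2%). No spot was saturated. The 75th percentile of the signal ranged from 454 to 815. Probes were named from their RefSeq accession through the gene table provided (assembly GRCz12tu, used for names only): 39952 of 42900 such probes matched. These had 1 symbol each, and 88339 probes had none. No genome build is given for the array in the sources used here, so no coordinates are printed. The probes of a symbol were centred and averaged (median 2 per gene; 3249 genes rest on 1 probe). This gave 85673 features, 13238 genes and 72435 unnamed probes. After outlier removal 126 probe values were missing. For a gene not well above background in a group, the fold was set against the higher of its own signal and the lowest signal well above background on each array. For gpr182 its own signal was the higher, so this gave the fitted fold and no separate lower bound.

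Groups were fitted together by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with Benjamini-Hochberg adjustment over all features of a comparison at 0.05), for each dose against 0 ppb, each pair of exposed doses, and all 4 doses by a moderated F test. The tests, the 37 gene lists (signalling and endocrine pathways, stress and metabolism, brain cell types, and tissues that a dissection can carry), the rule for naming genes and the settings listed at the end of the next paragraph, except those named as added, were fixed at the outset. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 37 lists. For camera the background was the 13238 genes with a symbol. The medians of all tested features given beside some lists also take in the 72435 unnamed probes, so they are not that background. No list passed fry against 0 ppb (lowest adjusted p = 0.970, 0.963 and 0.312 at 0.3, 3 and 30 ppb). Genes were named as follows for each dose against 0 ppb: the 12 largest rises and falls among genes past the threshold with all 4 exposed arrays on the same side of the control mean; if fewer than 20 qualified, filled to 20 by the smallest unadjusted p among genes changed at least 1.5-fold. Added were list members past the threshold, up to 4 members of each described list by smallest p, 10 genes of the F test, 5 per difference between exposed doses, and the 3 listed probes with the largest fold each way from the authors' deposited lists; clone and locus names were excluded. Python 3.11.15 with matplotlib 3.10.9 drew the figures.

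Slide and replicate number were the same: slide 1 held replicate 1 of every dose, and so on; replicates 1 and 2 were scanned on the first day and 3 and 4 on the second. Within a slide, each dose always had the same position, so position and dose cannot be told apart. Deviations from the group means correlated within each of the 24 same-slide pairs (r from 0.178 to 0.671 over all features, mean 0.435, against a mean of 0.323 for other slides of the same day and -0.379 across days), all above 0.1, so the numbers pair the arrays; 14 of 16 arrays correlated best with their own number. The first principal component held 59.6% of the variance over the 16 arrays and parted the scan days (scores of -175 to -33 and 39.9 to 275). Within each day of 8 arrays, in a test added after seeing the data, it followed the array median relative to the 75th percentile (r = -0.997 and -0.983, adjusted exact permutation p = 9.92e-05 and 0.000463). By rank rho was -1 and -0.929 (adjusted exact permutation p = 9.92e-05 and 0.00223), and r was -1.00 and -0.979 without the 2 farthest arrays. Both measures come from the same scaled signals, so they are not independent and this relation was partly built in. The planned fit has no block, and the fit with the replicate number as a block is an alternative. For 0.3 against 0 ppb the median standard error was 0.287 in the planned fit and 0.198 with the block. Slide differences thus stay in the standard errors and p-values of the planned fit. Its counts at an unadjusted p under 0.05 by limma lay below the 4284 expected by chance in every comparison. Other alternatives were quantile normalization, other probe filters, the slide as a random block (correlation 0.467), trended and robust moderation, single probes, the brightest probe of a gene, outlier flags kept, 8 arrays only, and each array left out. Normexp on the mean signal was not run, since that column is not among those used here; normexp on the median signal (offset 50), quantile normalization with the block, and each scan day alone were added after seeing the data.

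The scripts were tested on simulated data. For 30 ppb against 0 ppb over 85673 features, the fit without a block recovered 2%, 30%, 62% and 88% of genes changed 1.5, 2, 4 and 8-fold, with 0 false calls; with the block it recovered 14%, 46%, 84% and 100%, with 9 false calls. A shift of 0.4 added to the glucocorticoid list at 3 ppb was recovered (adjusted p = 1.22e-09 by limma's camera). Apart from slide effects the simulated genes varied independently of each other, so this does not test whether the preset correlation holds in the real arrays.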

Results

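RNA from single brains of 9-month-old male zebrafish (wild-type AB strain) was measured on 16 one-colour arrays, 1 brain per array. The fish had been exposed as embryos, from about 1 to 72 hours after fertilization, to atrazine, a triazine herbicide, at 0, 0.3, 3 or 30 ppb. They were rinsed when the exposure ended and were reared normally to the age of 9 months. Each dose had 4 brains (n = 4). The comparisons ask which adult brain transcripts differed after an exposure that ended in embryonic life. Of the 176026 spots of probes, between 82.4% and 95.03% per array were well above background, and the number of arrays limits the precision. The 8 arrays of the first scan day (replicates 1 and 2) had 91.3% to 95.03% of these spots well above background, and the 8 of the second (replicates 3 and 4) 82.4% to 87.8%. Each scan day held 2 arrays of every dose. Levels are log2 signals relative to the 75th percentile of the same array, and changes are exposed minus 0 ppb with their standard error (SE). Unless stated otherwise no gene named here passed the test across all genes. Slide counts set the exposed array of a slide against the 0 ppb array of that slide. The 20 genes named at each dose had all 4 exposed arrays on the same side of the control mean by choice. Their agreement over slides largely follows from that choice and is not separate evidence. It held on all 4 slides for 18, 15 and 17 of the 20 at 0.3, 3 and 30 ppb.

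Across the 3 exposed groups, 4 genes were among the 20 named at every dose. The transcript of itm2cb, a BRICHOS-domain membrane protein of the brain, was at 2.75 ± 0.25 (SD, n = 4) without atrazine and at 3.42 ± 0.35, 3.49 ± 0.27 and 3.45 ± 0.19 after 0.3, 3 and 30 ppb, changes of 0.67, 0.74 and 0.70 with an SE of 0.20 each. That of sult2st2, a cytosolic sulfotransferase, was 0.88, 0.78 and 0.61 higher (SE 0.20 each). Both had the higher level in the exposed array on all 4 slides at each dose, which the rule for naming genes made likely. Lower values were found for ak7a, an adenylate kinase of ciliated cells (-1.30, -1.14 and -1.30, SE 0.42), and for cdk5, a neuronal kinase (-1.16, -1.07 and -1.14, SE 0.34). The 4 unexposed brains spread widely in cdk5 (0.51 ± 0.96, SD) and the exposed groups did not (SDs of 0.17, 0.18 and 0.15). With only its brightest probe cdk5 stood at -0.19, -0.13 and -0.19. It was at -0.18, -0.16 and -0.22 on the first scan day and at -2.15, -1.99 and -2.06 on the second, and ak7a at -0.87 after 30 ppb on the first. Another 4 genes were named at 2 doses: sult2st1 (0.99 and 0.81 at 0.3 and 3 ppb, SE 0.27), igfbp7 (0.64 and 0.69, SE 0.24), the squalene epoxidase sqlea (0.75 and 0.79, SE 0.28), and the gamma-glutamyltransferase ggt5a (0.59 at 0.3 ppb and 0.89 at 30 ppb, SE 0.19). On the first scan day igfbp7 stood at 0.39 and 0.34, and on the second at 1.04 after 3 ppb. Because all 3 comparisons used the same 4 control brains, such repeats arise without any effect. Over 13238 genes the changes at 0.3 and 3 ppb correlated with r = 0.45, those at 0.3 and 30 ppb with r = 0.54 and those at 3 and 30 ppb with r = 0.60. Simulated groups with no effect against shared controls gave means of 0.53, 0.50 and 0.52 in 100 simulations. The covariances were 0.0218, 0.0255 and 0.0322 against simulated means of 0.0234, 0.0220 and 0.0235. With the controls split so that each comparison had its own pair, r ranged from -0.39 to 0.10, from -0.32 to 0.19 and from -0.22 to 0.19. These are the ranges over the 3 ways to split them, 1 of which set the controls of the scan days against each other. In every way the control pairs came from different slides, so slide differences entered both changes with opposite sign and lowered r. No value for this r without an effect was computed, so it cannot tell whether a shared response remains. All these r values are correlations across genes, which are not independent replicates.

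**Figure D1:**
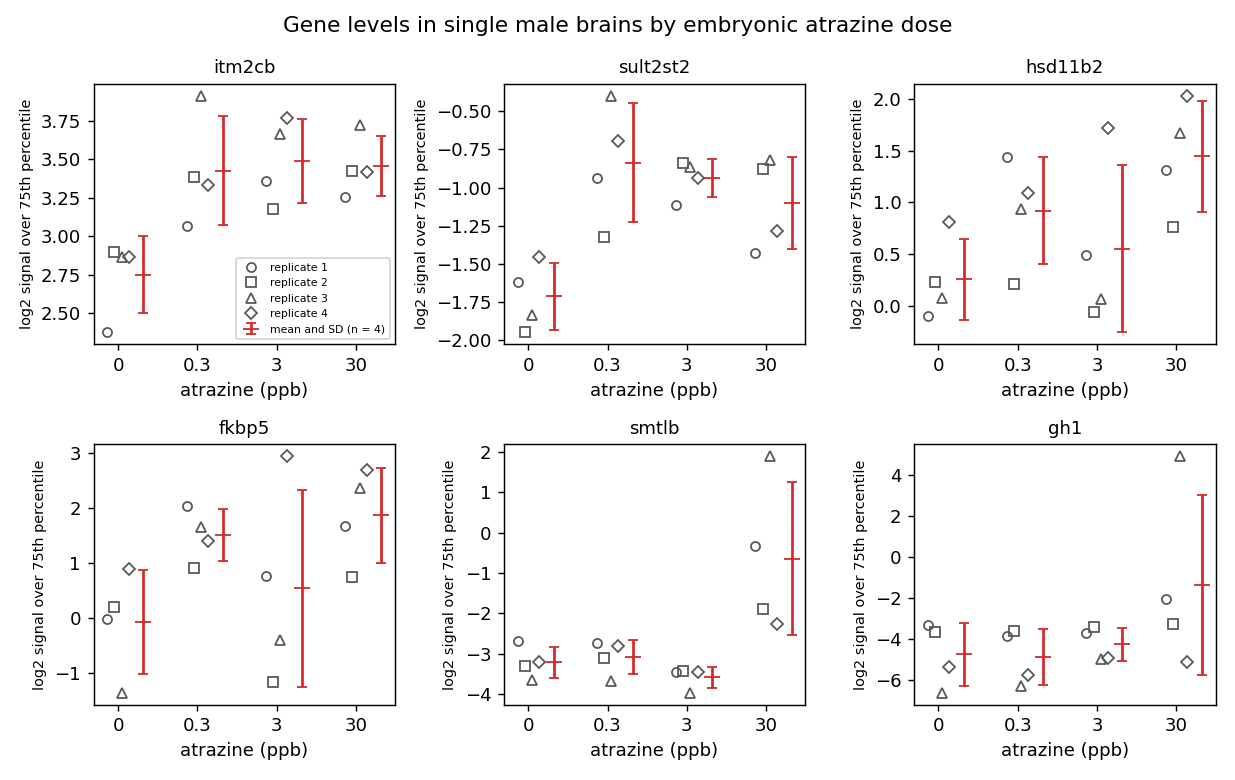
Levels of 6 genes (log2 signal over the 75th percentile of the array) in each brain by atrazine dose, with 1 symbol per replicate number and the group mean ± SD (n = 4) in red. The itm2cb and sult2st2 levels of exposed brains lie above those of the unexposed brain of the same slide, which the rule for naming genes made likely. In gh1, 30 ppb replicate 3 stands far above all other arrays.

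After 0.3 ppb, the genes of cholesterol synthesis were higher as a group: 21 of 24 measured members lay above 0, with a median change of 0.21 (p = 0.205 with an estimated correlation). Among them were hsd17b7 (0.47 ± 0.15), sqlea and the farnesyl diphosphate synthase gene fdps (0.31 ± 0.16). Markers of blood vessels and pericytes were higher by a median of 0.18 (22 of 26 above 0; p = 0.0726 with an estimated correlation), with the glucose transporter slc2a1a at 0.42 ± 0.17, the endothelial receptor tek at 0.42 ± 0.17 and plvapa at 0.32 ± 0.14. Genes of the aryl hydrocarbon receptor and xenobiotic metabolism were higher by a median of 0.11 (22 of 27 above 0; p = 0.137 with an estimated correlation), with nqo1 at 0.43 ± 0.17 beside sult2st1. Other genes with the smallest p-values were hsd17b3, of testosterone synthesis (0.96 ± 0.36), the antizyme gene oaz2b (0.95 ± 0.36), gpt (0.75 ± 0.28) and the Toll-like receptor tlr18 (0.64 ± 0.21) on the higher side. On the lower side were the germ-cell kinase gene mos (-0.71 ± 0.21) and prss35 (-0.64 ± 0.24). On the first scan day hsd17b3 stood at 0.63, oaz2b at 0.55 and mos at -0.37, and tlr18 was at 0.26 under normexp. In all, 16 of the 20 named genes were higher and 4 lower. By limma's camera with a preset correlation, 10 of the 37 gene lists fixed before the data were examined passed, 9 upward. They included cholesterol synthesis (adjusted p = 0.000334), vessels (adjusted p = 3.7e-05) and xenobiotic metabolism (adjusted p = 0.00699). With a correlation estimated from the arrays none passed (lowest adjusted p = 0.892). Normexp on the median signal gave these 3 medians of 0.14, 0.09 and 0.06. Within the scan days the cholesterol list had medians of 0.25 and 0.09 (adjusted p = 0.00548 and 0.00866), the vessel list 0.07 and 0.28 (adjusted p = 0.0635 and 0.000223), and the xenobiotic list 0.22 and 0.04 (adjusted p = 0.00123 and 0.258).

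The other 7 lists that passed at 0.3 ppb lost the call without 1 or more single arrays, and none passed with an estimated correlation (lowest adjusted p = 0.892). The glucocorticoid list (median 0.22, fkbp5 at 1.57 ± 0.74; 0.09 and 0.18 on the scan days, adjusted p = 0.321 and 0.172) ranged from 0.08 without 0 ppb replicate 2 to 0.49 without 0.3 ppb replicate 4. For the glucocorticoid list the call was lost without 0 ppb replicate 1 or 3 or 0.3 ppb replicate 3 (adjusted p up to 0.349). The unfolded protein response (median 0.10, calr3b at 0.34 ± 0.15; 0.05 and 0.19 on the scan days, adjusted p = 0.453 and 0.00269) ranged from 0.06 without 0.3 ppb replicate 3 to 0.13 without 0.3 ppb replicate 4. For the unfolded protein response the call was lost without 0.3 ppb replicate 3 (adjusted p = 0.361). Cell cycle genes (median 0.15, mcm2 at 0.43 ± 0.24; 0.25 and 0.10 on the scan days, adjusted p = 7.48e-05 and 0.214) ranged from 0.05 without 0 ppb replicate 3 to 0.23 without 0 ppb replicate 1, with 0.08 without 0.3 ppb replicate 1 and 0.09 without 0.3 ppb replicate 2. For cell cycle genes the call was lost without 0 ppb replicate 3 or 0.3 ppb replicate 2 (adjusted p up to 0.398). Oxidative phosphorylation (median 0.06, cycsb at 0.27 ± 0.13; 0.11 and 0.02 on the scan days, adjusted p = 0.0032 and 0.258) ranged from 0.03 without 0.3 ppb replicate 3 to 0.10 without 0 ppb replicate 3, with 0.03 without 0 ppb replicate 1 or 2. For oxidative phosphorylation the call was lost without 0 ppb replicate 1 or 2 or 0.3 ppb replicate 3 (adjusted p up to 0.944). Meninges (median 0.22, sparc at 0.37 ± 0.19; 0.18 and 0.13 on the scan days, adjusted p = 0.115 and 0.0524) ranged from 0.07 without 0 ppb replicate 3 to 0.34 without 0.3 ppb replicate 3, with 0.08 without 0.3 ppb replicate 1 and 0.14 without 0.3 ppb replicate 2. For meninges the call was lost without 0 ppb replicate 3 or 4 or 0.3 ppb replicate 1 or 4 (adjusted p up to 0.206). Keratinised epithelium (median 0.31, krt4 at 0.80 ± 0.55; 0.48 and 0.05 on the scan days, adjusted p = 0.000757 and 0.473) ranged from -0.05 without 0.3 ppb replicate 1 to 0.48 without 0.3 ppb replicate 4. For keratinised epithelium the call was lost without 0 ppb replicate 2 or 3 or 0.3 ppb replicate 1 (adjusted p up to 0.682). Ribosomal proteins (median -0.06, rpl10 at -0.23 ± 0.10; -0.04 and -0.08 on the scan days, adjusted p = 0.0463 and 0.0322) ranged from -0.10 without 0 ppb replicate 4 to -0.01 without 0 ppb replicate 3, with -0.04 without 0 ppb replicate 2. For ribosomal proteins the call was lost without 0 ppb replicate 3 (adjusted p = 0.982). Quantile normalization gave a ribosomal median of -0.02, and normexp gave 0.06 for the cell cycle and for the meninges. The median of all tested features was 0.01. Without 0.3 ppb replicate 1 the cholesterol median was 0.07, and without 0 ppb replicate 2 it was 0.13. The vessel median was 0.11 without 0 ppb replicate 3, and the xenobiotic median 0.21, 0.06 and 0.17 without 0 ppb replicate 1 and 0.3 ppb replicates 2 and 3. For single genes limma found 0 of 85673 past an adjusted p of 0.05, with 1897 at an unadjusted p under 0.05 (1277 higher and 620 lower; 4284 by chance) and 5437 with the slide as a block, still 0 after adjustment. Quantile normalization gave 4, and ended the calls of the glucocorticoid list (adjusted p = 0.05001) and ribosomal proteins (0.358). The meninges call ended under normexp and without a probe filter.

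After 3 ppb, cholesterol synthesis was again higher, with a median change of 0.12 and 16 of 24 members above 0 (p = 0.136 with an estimated correlation): sqlea, msmo1 (0.50 ± 0.20), fdps (0.36 ± 0.16) and hsd17b7 (0.33 ± 0.15). Skeletal muscle genes were higher by a median of 0.12 and a mean of 0.35 (23 of 35 above 0; p = 0.231 with an estimated correlation), led by the parvalbumin genes pvalb2 (2.15 ± 0.82) and pvalb1 (1.77 ± 0.62), actc1b (1.08 ± 0.43) and tnni2b.2 (1.26 ± 0.57). These are genes of striated muscle, a tissue beside the brain, and their levels differed widely between brains. Another parvalbumin gene among the 20 named, pvalb9, went the other way, with changes from -2.00 to -1.14 over the fits without 1 array. Other genes with small p-values were the choline phosphodiesterase gene enpp6 (1.22 ± 0.43) and lims2 (1.43 ± 0.50), higher on all 4 slides. Lower on all 4 were the homeobox gene gsc (-1.09 ± 0.31), the mitochondrial import gene timm8a (-0.64 ± 0.16), hnmt, which inactivates histamine (-0.70 ± 0.22), nat10 (-0.61 ± 0.20) and rpp21 (-0.61 ± 0.18). The scan days gave -0.43 and -1.75 for gsc, the first gave 1.05 for pvalb1 (0.99 under normexp), and the second -0.39 for rpp21. Probes of enpp6 in the authors' deposited list stood at 3.20 and 3.03, against 1.22 over all its probes, so its other probes changed less. Of the named genes, 9 of 20 were higher and 11 lower. With the preset correlation 12 lists passed, 11 upward, with adjusted p = 1.54e-05 for cholesterol synthesis and 3.27e-05 for muscle by limma's camera. With an estimated correlation none passed (lowest adjusted p = 0.667). After quantile normalization 5 of the 12 kept the call. The muscle median was then 0.26 (adjusted p = 6.07e-05), and 0.03 under normexp. The cholesterol list held on both scan days (medians 0.17 and 0.09, adjusted p = 0.00118 and 0.000364). Muscle passed on the second only (0.09 and 0.31, adjusted p = 0.322 and 3.87e-09). Without single arrays the cholesterol median ranged from 0.07 (0 ppb replicate 2) to 0.27 (0 ppb replicate 1), with 0.22 without 3 ppb replicate 3. That of muscle was 0.00 without 0 ppb replicate 3, 0.02 without 3 ppb replicate 2, 0.26 without 0 ppb replicate 1 and 0.23 without 3 ppb replicate 1 or 4, each still past the threshold.

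The other 10 lists at 3 ppb also depended on single arrays, and none passed with an estimated correlation (lowest adjusted p = 0.667). GABA signalling (median 0.13; 0.10 and 0.03 on the scan days, adjusted p = 0.00359 and 0.279) ranged from 0.06 without 0 ppb replicate 2 to 0.19 without 0 ppb replicate 4. For GABA signalling the call was lost without 0 ppb replicate 2 or 3 ppb replicate 4 (adjusted p up to 0.392). Oxidative phosphorylation (median 0.04, uqcrq at 0.54 ± 0.22; 0.13 and -0.05 on the scan days, adjusted p = 2.07e-07 and 0.735) ranged from 0.01 without 0 ppb replicate 2 to 0.07 without 0 ppb replicate 3, with 0.02 without 0 ppb replicate 1 and 0.07 without 0 ppb replicate 4. For oxidative phosphorylation the call was lost without 0 ppb replicate 1 or 2 (adjusted p up to 0.309). The glucocorticoid list (median 0.17; -0.17 and 0.13 on the scan days, adjusted p = 0.828 and 0.00253) ranged from 0.00 without 3 ppb replicate 4 to 0.21 without 0 ppb replicate 4. For the glucocorticoid list the call was lost without 0 ppb replicate 1, 2 or 3 or 3 ppb replicate 3 or 4 (adjusted p up to 0.425). Neurons (median 0.02; -0.02 and 0.01 on the scan days, adjusted p = 0.283 and 0.0514) ranged from -0.02 without 0 ppb replicate 4 to 0.06 without 0 ppb replicate 3, with -0.01 without 3 ppb replicate 1, 0.01 without 0 ppb replicate 2 or 3 ppb replicate 3, 0.06 without 3 ppb replicate 2 and 0.05 without 3 ppb replicate 4. For neurons the call was lost without 0 ppb replicate 1 or 2 or 3 ppb replicate 3 or 4 (adjusted p up to 0.274). The unfolded protein response (median 0.06; 0.02 and 0.07 on the scan days, adjusted p = 0.327 and 0.0163) ranged from 0.02 without 3 ppb replicate 3 to 0.07 without 3 ppb replicate 4, with 0.03 without 0 ppb replicate 4. For the unfolded protein response the call was lost without 0 ppb replicate 1, 2 or 4 or 3 ppb replicate 3 or 4 (adjusted p up to 0.274). The circadian clock (median 0.05; -0.08 and 0.18 on the scan days, adjusted p = 0.337 and 0.00845) ranged from -0.04 without 0 ppb replicate 4 to 0.19 without 0 ppb replicate 2, with 0.10 without 0 ppb replicate 1, 0.13 without 3 ppb replicate 1, 0.02 without 3 ppb replicate 2, 0.11 without 0 ppb replicate 3 and 0.12 without 3 ppb replicate 4. For the circadian clock the call was lost without 0 ppb replicate 1 or 4 or 3 ppb replicate 3 or 4 (adjusted p up to 0.19). Heat shock genes (median 0.09; 0.02 and 0.08 on the scan days, adjusted p = 0.247 and 0.0168) ranged from -0.01 without 0 ppb replicate 4 to 0.17 without 3 ppb replicate 4, with 0.04 without 3 ppb replicate 2, 0.02 without 0 ppb replicate 3 and 0.00 without 3 ppb replicate 3. For heat shock genes the call was lost without 0 ppb replicate 2, 3 or 4, 3 ppb replicate 1 or 3 or 30 ppb replicate 1 or 4 (adjusted p up to 0.207). Oligodendrocytes (median 0.07; 0.10 and 0.08 on the scan days, adjusted p = 0.105 and 0.18) ranged from -0.02 without 0 ppb replicate 2 to 0.11 without 0 ppb replicate 1, with -0.01 without 3 ppb replicate 1, 0.11 without 3 ppb replicate 2, 0.02 without 0 ppb replicate 3 or 3 ppb replicate 4 and 0.04 without 0 ppb replicate 4. For oligodendrocytes the call was lost without 0 ppb replicate 2 or 3, 3 ppb replicate 4 or 30 ppb replicate 1 (adjusted p up to 0.392). Vessels (median 0.04; -0.03 and 0.21 on the scan days, adjusted p = 0.774 and 0.000326) ranged from -0.02 without 0 ppb replicate 3 to 0.13 without 0 ppb replicate 1, with 0.09 without 0 ppb replicate 2 or 4, 0.10 without 3 ppb replicate 2 and 0.07 without 3 ppb replicate 4. For vessels the call was lost without 0 ppb replicate 3 or 3 ppb replicate 3 or 4 (adjusted p up to 0.367). Ribosomal proteins (median -0.12, 65 of 70 below 0, where the median of all tested features was -0.09; -0.05 and -0.19 on the scan days, adjusted p = 0.824 and 2.07e-05) ranged from -0.16 without 0 ppb replicate 4 to -0.06 without 0 ppb replicate 3. For ribosomal proteins the call was lost without 0 ppb replicate 3 (adjusted p = 0.13). After quantile normalization the medians of neurons, the unfolded protein response, the clock, oligodendrocytes and vessels were 0.04, 0.03, 0.17, 0.12 and 0.18. Normexp gave 0.07 for oxidative phosphorylation, 0.11 for the glucocorticoid list, 0.04 for neurons, 0.02 for heat shock genes and 0.01 for vessels. The vessel median was 0.10 without a probe filter and 0.03 with only probes well above background on all 16 arrays. No single gene of 85673 passed limma's adjusted test. An unadjusted p under 0.05 was found for 1518 (847 higher and 671 lower). With the slide as a block it was found for 5678 (2008 higher and 3670 lower), so the larger side turned. Quantile normalization also gave 0 past the adjusted test. It ended the calls of 7 lists: heat shock (adjusted p = 0.112), glucocorticoid (0.152), oligodendrocytes (0.152), the circadian clock (0.161), the unfolded protein response (0.192), neurons (0.238) and oxidative phosphorylation (0.078). Without a probe filter the glucocorticoid and heat shock lists did not pass either (0.0686 and 0.0505).

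After 30 ppb, the glucocorticoid receptor and response genes were higher, with 15 of 17 members above 0 and a median change of 0.37. With an estimated correlation the list did not pass (p = 0.00154, adjusted p = 0.0571). Its members with the smallest p-values were hsd11b2, which inactivates cortisol, at 1.18 ± 0.39, the receptor chaperone gene fkbp5 at 1.93 ± 0.74 and klf9 at 1.12 ± 0.52, and the mineralocorticoid receptor gene nr3c2 at -0.38 ± 0.20. hsd11b2 and fkbp5 were higher on all 4 slides, and klf9 on 3, with -0.43 in both arrays of slide 2. Ribosomal protein genes were lower by a small amount, with 68 of 70 members below 0 and a median of -0.14 (p = 0.0811 with an estimated correlation; -0.07 after quantile normalization, adjusted p = 0.00026), such as rplp2 (-0.35 ± 0.13), rpl34 (-0.28 ± 0.11) and rps3 (-0.24 ± 0.10). The median of all tested features was -0.06. Among the 20 named genes the largest change was that of smtlb, which encodes the fish pituitary hormone somatolactin beta, at 2.57 ± 0.66 (5.94-fold), or 1.72 without 30 ppb replicate 3 and 1.83 under normexp. It was higher on all 4 slides, the gain ran from 0.95 to 5.54, and the scan days gave 1.89 and 3.25. Higher values were also found for the tight junction gene cldn11a (0.91 ± 0.32), the deubiquitinase gene usp2a (0.78 ± 0.24) and hif1al (0.72 ± 0.25). Lower ones were found for nt5e, which forms adenosine (-1.57 ± 0.50), the homeobox genes nkx2.4b (-0.89 ± 0.25) and en1b (-0.66 ± 0.18) and the replication helicase gene mcm7 (-0.73 ± 0.23). On the first scan day alone usp2a stood at 0.30, hif1al at 0.36 and cldn11a at 0.59, and on the second usp2a at 1.25 and en1b at -0.43. mcm7 was at -0.44 without 30 ppb replicate 4. Of the 20 named genes, 12 were higher and 8 lower. gpr182 was not well above background without atrazine and was so on 3 of the 4 arrays of 30 ppb, with a fitted fold of 1.73 that is not a lower bound. Its fitted log2 change was 0.79, but 0.07 under normexp and 0.48 without 30 ppb replicate 2.

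By limma's camera with the preset correlation the adjusted p was 0.000223 for the glucocorticoid list and 3.71e-16 for ribosomal proteins. At this dose 10 lists passed, 7 upward. With an estimated correlation none did. The ribosomal list was lower on both scan days (-0.06 and -0.23, adjusted p = 3.36e-05 and 0.00116) and at -0.09 without 0 ppb replicate 3. The glucocorticoid list had a median of 0.09 on the first scan day (adjusted p = 0.745) and 0.27 on the second (adjusted p = 0.000162), 0.00, 0.20, 1.22 and 0.35 on the 4 slides, 0.23 without 30 ppb replicate 3 (adjusted p = 0.0488), and 0.22 under normexp.

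The 8 other lists at 30 ppb each lost the call without some arrays, and none passed with an estimated correlation (lowest adjusted p = 0.986). Pituitary genes (median 0.26, 9 of 13 above 0; 0.40 and 0.15 on the scan days, adjusted p = 0.0161 and 0.112) ranged from 0.09 without 30 ppb replicate 1 to 0.52 without 0 ppb replicate 1, with 0.10 without 30 ppb replicate 2. For pituitary genes the call was lost without 0 ppb replicate 4 or 30 ppb replicate 1 (adjusted p up to 0.0739). Erythrocyte genes (median -0.32, 18 of 19 below 0, the globin gene ba1l at -0.51 ± 0.16; -0.28 and -0.44 on the scan days, adjusted p = 0.00375 and 0.462) ranged from -0.65 without 30 ppb replicate 2 to -0.20 without 0 ppb replicate 1, with -0.54 without 0 ppb replicate 3. For erythrocyte genes the call was lost without 0 ppb replicate 1 or 4 or 30 ppb replicate 1 (adjusted p up to 0.728). Oxidative phosphorylation (median -0.07; 0.02 and -0.18 on the scan days, adjusted p = 0.461 and 0.143) ranged from -0.11 without 0 ppb replicate 1 to -0.03 without 0 ppb replicate 3, with -0.04 without 30 ppb replicate 4. For oxidative phosphorylation the call was lost without 0 ppb replicate 3 or 4 or 30 ppb replicate 1 or 2 (adjusted p up to 0.497). Heat shock genes (median 0.11; 0.09 and 0.19 on the scan days, adjusted p = 0.858 and 0.000637) ranged from 0.04 without 0 ppb replicate 3 to 0.18 without 30 ppb replicate 4, with 0.04 without 30 ppb replicate 2. For heat shock genes the call was lost without 0 ppb replicate 4 or 30 ppb replicate 3 (adjusted p up to 0.671). Xenobiotic metabolism (median 0.08; 0.28 and -0.13 on the scan days, adjusted p = 0.0215 and 0.455) ranged from -0.05 without 0 ppb replicate 3 to 0.18 without 30 ppb replicate 3, with 0.16 without 0 ppb replicate 1, 0.00 without 30 ppb replicate 1, 0.02 without 0 ppb replicate 2, -0.04 without 30 ppb replicate 2, 0.05 without 0 ppb replicate 4 and 0.14 without 30 ppb replicate 4. For xenobiotic metabolism the call was lost without 0 ppb replicate 1, 2 or 3, 0.3 ppb replicate 2 or 30 ppb replicate 1, 2, 3 or 4 (adjusted p up to 0.195). Vessels (median 0.08; 0.21 and -0.03 on the scan days, adjusted p = 0.017 and 0.462) ranged from -0.01 without 0 ppb replicate 3 to 0.18 without 30 ppb replicate 3, with 0.03 without 30 ppb replicate 1 and 0.16 without 30 ppb replicate 4. For vessels the call was lost without 0 ppb replicate 1 or 3 or 30 ppb replicate 1 or 2 (adjusted p up to 0.46). Cholesterol synthesis (median 0.09; 0.30 and -0.18 on the scan days, adjusted p = 0.00914 and 0.908) ranged from -0.07 without 30 ppb replicate 1 to 0.21 without 0 ppb replicate 1, with 0.02 without 0 ppb replicate 2, 0.01 without 30 ppb replicate 2, 0.04 without 0 ppb replicate 3, 0.19 without 30 ppb replicate 3, 0.06 without 0 ppb replicate 4 and 0.14 without 30 ppb replicate 4. For cholesterol synthesis the call was lost without 0 ppb replicate 2, 3 or 4 or 30 ppb replicate 1 or 2 (adjusted p up to 0.728). Muscle (median 0.13; 0.57 and -0.37 on the scan days, adjusted p = 7.47e-05 and 0.607) ranged from -0.10 without 30 ppb replicate 1 to 0.39 without 30 ppb replicate 3, with 0.27 without 0 ppb replicate 1, -0.02 without 30 ppb replicate 2, -0.01 without 0 ppb replicate 3, 0.08 without 0 ppb replicate 4 and 0.29 without 30 ppb replicate 4. For muscle the call was lost without 0 ppb replicate 2, 3 or 4 or 30 ppb replicate 1 (adjusted p up to 0.849). In the pituitary list smtlb was the 1 gene of any list past the threshold adjusted over the list alone. Quantile normalization gave medians of -0.05 for oxidative phosphorylation, 0.13 for vessels and 0.23 for muscle. Normexp gave 0.10 for pituitary genes, 0.05 for heat shock genes, -0.05 for xenobiotic metabolism, 0.03 for vessels and 0.04 for cholesterol synthesis and for muscle. The pituitary median was 0.41 without a probe filter and 0.11 with only probes well above background on all 16 arrays. With the slide as a block cholesterol synthesis and muscle also no longer passed (adjusted p = 0.0522 and 0.075). No single gene passed limma's adjusted test. Of 85673 features, 2121 had an unadjusted p under 0.05 (1226 higher and 895 lower). With the block 6372 did (2938 higher and 3434 lower), so the larger side turned. Quantile normalization gave 0 past the adjusted test. It ended the calls of oxidative phosphorylation (adjusted p = 0.197) and vessels (0.144), as did normexp (0.368 and 0.29), which also ended that of xenobiotic metabolism (0.0675). With only probes well above background on all 16 arrays, pituitary genes (0.0746) and cholesterol synthesis did not pass.

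**Figure D2:**
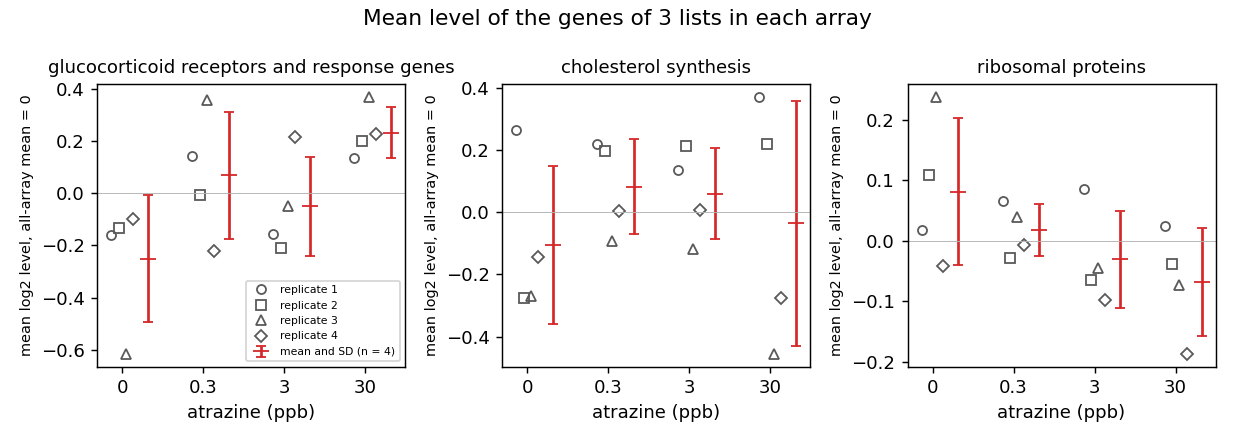
Mean log2 level of the genes of 3 lists on each array (mean of all 16 arrays set to 0) by atrazine dose, with 1 symbol per replicate number and the group mean ± SD (n = 4) in red. The glucocorticoid list is lowest in 0 ppb replicate 3, at -0.62, and lies between 0.14 and 0.37 in the 4 brains of 30 ppb.

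The 3 exposed doses were also set against each other. The median of all tested features was -0.08 for 3 against 0.3 ppb, -0.06 for 30 against 0.3 ppb and 0.02 for 30 against 3 ppb. Genes of oxidative phosphorylation were lower after 30 ppb than after 3 ppb, in 35 of 35 members (median -0.12), for example uqcrq (-0.54 ± 0.22) and cox5b2 (-0.62 ± 0.27). Against 0.3 ppb they were lower in 34 of 35 members (median -0.14), for example cox7a2a (-0.29 ± 0.12). The adjusted p by limma's camera was 1.07e-16 and 5.71e-14, but neither passed with an estimated correlation (adjusted p = 0.251 and 0.863). Both held on each scan day (-0.09 and -0.14 against 3 ppb, -0.08 and -0.19 against 0.3 ppb) and without any 1 array, the lowest size being -0.09 against 0.3 ppb without 0.3 ppb replicate 3; after quantile normalization the median against 3 ppb was -0.08. Markers of motile cilia and ependyma, the lining of the ventricles, were lower at 3 than at 0.3 ppb in all 16 measured members (median -0.30; daw1 -0.53 ± 0.22, capsla -0.62 ± 0.27; adjusted p = 7.3e-05, p = 0.171 with an estimated correlation), on both scan days (-0.36 and -0.20). The median was -0.17 and -0.18 without 0.3 ppb replicate 1 and 3 ppb replicate 4, and -0.18 after quantile normalization. Photoreceptor genes were lower in the same comparison (median -0.40, 34 of 40 below 0; adjusted p = 0.00591, p = 0.435 with an estimated correlation; -0.40 and -0.28 on the scan days), such as pde6a (-0.56 ± 0.27). Their median was -0.21 after quantile normalization, -0.26 under normexp and -0.60 without 0.3 ppb replicate 3. They lost the call without 0.3 ppb replicate 1 (median -0.18, adjusted p = 0.0557) or 4 (0.0639) or 3 ppb replicate 3 (0.143). Lens genes were lower by a median of -0.21 (26 of 31 below 0; adjusted p = 0.0481, p = 0.496 with an estimated correlation; -0.35 and -0.19 on the scan days, adjusted p = 0.0017 and 0.105). Their call ended after quantile normalization (median 0.00, adjusted p = 0.276) and without a probe filter (0.105). It also ended without 0.3 ppb replicate 1 (median -0.09, adjusted p = 0.265) or 2 (0.16), 3 ppb replicate 3 (-0.13, 0.143) or 4 (0.152), or replicate 4 of 0 or 30 ppb (0.0515 and 0.0554). The median was -0.34 and -0.41 without 3 ppb replicate 1 and 0.3 ppb replicate 3. Pituitary genes were higher at 30 than at 3 ppb by a median of 0.69 (10 of 13; adjusted p = 0.000524, but no call with an estimated correlation, adjusted p = 0.302), with 0.54 on the first scan day and 0.40 on the second (adjusted p = 0.0128 and 0.0538), 0.40 after quantile normalization and 0.39 under normexp. Of the other lists that passed between doses, 3 did so in all 16 fits without 1 array. Skeletal muscle was higher at 3 than at 0.3 ppb (median 0.17, adjusted p = 6.12e-05, p = 0.222 with an estimated correlation; -0.05 and 0.40 on the scan days, adjusted p = 0.789 and 4.15e-14). Its median was 0.07 without 3 ppb replicate 2, 0.06 without 0.3 ppb replicate 3, 0.30 after quantile normalization, 0.11 under normexp and 0.09 with only probes well above background on all 16 arrays. Ribosomal proteins were lower at 30 than at 0.3 ppb (median -0.08, against -0.06 over all features, adjusted p = 8.47e-07, p = 0.248 with an estimated correlation; -0.02 and -0.14 on the scan days, adjusted p = 0.00943 and 0.173). Its median was -0.05 without 30 ppb replicate 4 and after quantile normalization. Oligodendrocyte genes were lower at 30 than at 3 ppb (median -0.12, adjusted p = 0.000815, but no call with an estimated correlation, adjusted p = 0.251; -0.0049 and -0.17 on the scan days, adjusted p = 0.0136 and 0.23). Its median was -0.18, -0.06 and -0.03 without 30 ppb replicates 2, 3 and 4. In all, 7, 10 and 7 lists passed with the preset correlation for 3 against 0.3, 30 against 0.3 and 30 against 3 ppb, and 6, 6 and 9 with the block. With an estimated correlation none passed (lowest adjusted p = 0.913, 0.863 and 0.239). The lists not described here lost the call without 1 or more arrays. Among single genes, smtlb was 2.94 ± 0.66 (2.09 without 30 ppb replicate 3, 2.08 under normexp, 2.34 and 3.53 on the scan days), the arginine vasopressin gene avp 1.88 ± 0.54 and gsc 1.26 ± 0.31 higher at 30 than at 3 ppb. The glutathione transferase gene gstm.3 (-0.56 ± 0.23), the glucuronosyltransferase gene ugt5c2 (-0.73 ± 0.19) and cyp2ad6 (-1.004 ± 0.27, or -0.66 under normexp) were lower at 3 than at 0.3 ppb, and prdx1 was lower at 30 than at 0.3 ppb (-0.86 ± 0.23). In the test over all 4 doses the smallest p-values belonged to ggt5a, smtlb, tlr18, sult2st2, myclb, timm8a, the water channel gene aqp1a.1, coro2aa, gsc and itm2cb. The changes of aqp1a.1 were -0.49, -0.57 and -0.56 after 0.3, 3 and 30 ppb. By limma 0 of 85673 passed in each of these 4 tests, with 2065 (3 against 0.3 ppb), 821 (30 against 0.3), 1263 (30 against 3) and 1232 (all doses) at an unadjusted p under 0.05, and 6486, 3358, 4414 and 5559 with the block. Quantile normalization gave 19, 0, 8 and 13, none of them a probe with a gene symbol.

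The following 9 lists had no call against 0 ppb. At 0.3, 3 and 30 ppb the median changes were 0.05, 0.00 and -0.08 for serotonin signalling, -0.01, -0.09 and -0.04 for dopamine and noradrenaline, 0.04, 0.01 and -0.03 for glutamate. They were 0.03, -0.07 and -0.09 for hypothalamic neuropeptides and the reproductive axis, 0.02, -0.11 and 0.07 for sex steroid receptors and synthesis, 0.03, -0.05 and -0.07 for thyroid hormone signalling, and 0.03, 0.02 and -0.05 for DNA methylation and histone modification. Those of the oxidative stress response were -0.04, -0.03 and -0.04, and those of inflammation and interferon -0.04, -0.12 and -0.01. Among these lists the lowest adjusted p by limma's camera was 0.222. Acetylcholine signalling stood at -0.03, -0.01 and -0.20, immediate early genes at -0.06, 0.01 and -0.09, radial glia and progenitors at 0.00, -0.09 and -0.11, and microglia and leukocytes at -0.04, 0.09 and -0.01, also without a call against 0 ppb. Between doses, acetylcholine signalling was lower at 30 than at 3 ppb (median -0.13, 8 of 12 below 0; adjusted p = 0.00309, but no call with an estimated correlation, adjusted p = 0.288; -0.04 and -0.27 on the scan days, adjusted p = 0.12 and 0.0369), such as chrna4b (-0.36 ± 0.15). It lost the call without 30 ppb replicate 2 (0.0648), and its median was -0.21 and -0.19 without 30 ppb replicate 1 and 3 ppb replicate 3. Microglia and leukocyte genes were higher at 3 than at 0.3 ppb (median 0.15, 14 of 24 above 0; adjusted p = 0.035, p = 0.18 with an estimated correlation; 0.06 and 0.14 on the scan days, adjusted p = 0.0391 and 0.0869). They lost the call with the block (0.0573) and without 0.3 ppb replicate 1 (median 0.05, adjusted p = 0.477) or 3 (0.09, 0.204) or 3 ppb replicate 4 (0.02, 0.804), and stood at 0.38 without 0.3 ppb replicate 4. They also passed at 30 against 0.3 ppb (median 0.05, adjusted p = 0.0324, p = 0.222 with an estimated correlation), but not with the block (0.0504) or after quantile normalization (median 0.09, adjusted p = 0.0833). Their median there (0.05; 0.13 and 0.07 on the scan days, adjusted p = 0.573 and 0.0456) ranged from -0.03 without 0.3 ppb replicate 3 to 0.19 without 0.3 ppb replicate 4, with -0.01 without 0.3 ppb replicate 1, 0.12 without 30 ppb replicate 1, 0.08 without 0.3 ppb replicate 2 and 0.09 without 30 ppb replicate 3 or 4, and lost the call without 0.3 ppb replicate 1, 2 or 3 or 30 ppb replicate 3 or 4 (adjusted p up to 0.943). Motile cilia genes stood at 0.14, -0.19 and -0.11. With the slide as a block their list passed at 0.3 ppb (adjusted p = 0.0144 by limma's camera, 0.0595 without the block) and at 3 ppb (0.0249, 0.147 without). So did photoreceptors at 0.3 ppb (median 0.11, adjusted p = 0.0466) and the circadian clock at 30 ppb (median 0.09, adjusted p = 0.0417). With the block and an estimated correlation these 4 had p = 0.312, 0.361, 0.515 and 0.0515. Markers of other tissues that a brain dissection could carry, namely lens (median -0.18 at 3 ppb), photoreceptors (-0.28), the pineal organ (-0.21), liver and plasma proteins (-0.24) and pancreatic enzymes (-0.28), did not pass against 0 ppb at any dose without the block.

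The authors' deposited tables list probes changed at least 1.5-fold. They hold 514 at 0.3 ppb (460 up and 54 down), 339 at 3 ppb (142 and 197) and 464 at 30 ppb (388 and 76). Only 96, 83 and 96 of these carry a gene symbol. The largest listed folds with a symbol were 3.25 for ugt2a3 (up) and 5.87 for cdk5 (down) at 0.3 ppb, 9.22 for enpp6 (up) and 9.31 for ggcta (down) at 3 ppb, and 5.94 for smtlb (up), 5.25 for tnni2b.2 (up) and 5.87 for cdk5 (down) at 30 ppb. Each is the fold of a single probe, and other probes of cdk5 and enpp6 changed less. Every listed probe had the same direction in the probe-level fit, with a mean difference in log2 change of 0.0024, 0.0042 and 0.00012. The lists came from these same arrays, so the same direction is not independent evidence. The unadjusted p-values that follow are not either, since the probes had been listed for a large change. Of the listed probes, 432, 254 and 325 had an unadjusted p under 0.05 by limma, and 0 an adjusted p under 0.05 with or without the block. The authors' deposited tables share 78 up-listed probes between 0.3 and 3 ppb, 287 between 0.3 and 30 ppb and 84 between 3 and 30 ppb; 59 were up at all 3 doses and 10 down. These tables too rest on shared controls, and no value for this sharing without an effect was computed. Opposite ways in the authors' deposited tables went 58 probes at 0.3 and 3 ppb, 37 at 3 and 30 ppb and 5 at 0.3 and 30 ppb.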

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

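The tests of slides and scan days, of pituitary tissue, and of other splits for the counts of genes past the threshold were chosen after the results were seen, and the glucocorticoid list was picked for the splits after its list test was known. Groups of 4 arrays were searched for an array far from the rest: the gap to its neighbour was divided by the range of the group. In 396 such groups 24 stood out (6.06%), where chance gives about 1 in 20.

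Among array measures, 3 ppb replicate 2 had the high 75th percentile signal (0.8486) and 30 ppb replicate 1 the high share of the brightest probes (0.8621). Among list levels, 0 ppb replicate 3 was low in the glucocorticoid list (0.8873), vessels (0.8332) and erythrocytes (0.8315), and 0.3 ppb replicate 1 was high in GABA (0.9319) and acetylcholine signalling (0.8411). GABA signalling was low in 0 ppb replicate 2 (0.8792), heat shock genes in 3 ppb replicate 4 (0.8987) and oligodendrocyte genes in 0.3 ppb replicate 4 (0.8606). Oxidative phosphorylation was high in 0.3 ppb replicate 3 (0.8529) and erythrocyte genes in 30 ppb replicate 2 (0.8931). Among single genes, 0 ppb replicate 1 was low in itm2cb (0.9328) and ak7a (0.9501). High levels were found for ggt5a (0.9205) and ccn2b (0.8653) in 0.3 ppb replicate 1, prss35 in 0.3 ppb replicate 2 (0.8514), hif1al in 3 ppb replicate 4 (0.8863) and htra2-6 in 30 ppb replicate 3 (0.891). Low levels were found for ggt5a in 3 ppb replicate 1 (0.8368), smtlb in 3 ppb replicate 3 (0.9426), ccdc82 in 0.3 ppb replicate 3 (0.8339), en1b in 30 ppb replicate 1 (0.9045) and prdx1 in 30 ppb replicate 3 (0.8312).

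The glucocorticoid list was higher at 30 ppb, and no single array accounts for all of it. The lowest median over the 16 fits without 1 array was 0.23, without 30 ppb replicate 3, against 0.37 with all (adjusted p = 0.0488 and 0.000223 by limma's camera). That array also lay farthest out on the first principal component (275). Such fits do not take out the 30 and 0 ppb arrays of slide 3 together. There the difference was largest (1.22), and 0 ppb replicate 3 was flagged as low (0.8873). A shift shared by the arrays of a slide or scan day cancels in this comparison, since each slide held 1 array of every dose, and with the slide as a block the list still passed (adjusted p = 0.000149 by limma's camera), but not with the block and an estimated correlation (adjusted p = 0.562). A difference within slides stays open, since position on the slide was the same as dose: the list median of the 30 ppb array lay above that of the 0 ppb array on 4 of 4 slides, by 0.00 to 1.22, and the call was absent within the first scan day (adjusted p = 0.745). The bound for that test was tightened after those values were seen. Of the 35 splits of the 8 arrays, 1, the real one, gave so small a p (-log10 p of 4.92, highest other 4.84), but these splits take no account of the pairing or of the choice among 37 lists; among the 8 splits that part all pairs of a slide it was again 1 (highest other 4.42), too few to say whether chance is excluded. An effect of the exposure may remain as a hypothesis.

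The smtlb transcript was higher at 30 ppb, and more pituitary tissue in those samples may account for part of it. The median change of the other 6 pituitary hormone genes was 0.647 (SD 1.28), against a bound of 1.29 derived from the change of smtlb (2.57), below it by less than their spread, so the test leaves this open. The 30 ppb replicate 3 array had the highest level of the 16 in smtlb (1.89), gh1 (4.93), cga (0.35), pomca (2.98) and fshb (-1.43). The same array had the lowest level of the 16 in smtla (-3.87), the other somatolactin gene. In prl2 it stood at -0.19, below 0.3 ppb replicate 1 (0.02). In the other 3 brains of 30 ppb smtlb stood at -0.32, -1.89 and -2.26, against -2.70 to -3.65 without atrazine. On slide 4 smtlb was at -2.26 against -3.22 without atrazine, but cga was at -4.76 against -4.14 and pomca at -0.97 against 0.05. There fshb, prl2 and smtla were lower too, and gh1 was higher (-5.11 against -5.35). On slides 1 and 2 gh1, fshb, cga and prl2 were higher after 30 ppb. Of these slides, pomca was higher only on slide 1 and smtla only on slide 2. Slide 4 is 1 pair of arrays, so it does not settle the question. No median without replicate 3 was computed. An effect of the exposure on the hormone itself was not tested apart from the amount of pituitary tissue.

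Probes in the authors' deposited lists often stood apart from other probes of their gene. Over 256 listed probes with a measured sibling, the listed median was 0.74 and that of the siblings 0.42, a ratio of 0.564 (95% interval 0.466 to 0.679, added after the ratio was seen); in 229 cases the siblings went the same way. A difference particular to a probe, such as a sequence variant under it, may account for part of this, and the interval spans the bound set for excluding it, so this stays open. Selecting probes for a large change also lowers such a ratio. No biological explanation was tested.

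Other splits of the arrays were set beside each count. Genes past the threshold numbered 0 in every comparison, so all 35 of 35 splits (and 100 of 100 drawn for the 4 doses) gave as many. The highest other counts by limma were 0, 2 and 33913 for 0.3, 3 and 30 ppb against 0 ppb, 2, 35684 and 25409 for 0.3 with 3, 0.3 with 30 and 3 with 30 ppb, and 25299 for all doses. For 30 ppb against 0, and for 30 against 0.3 and 3 ppb, that split parted the scan days, which points to a structure of the samples; with the slide as a block the real counts were 0. At an unadjusted p under 0.05, 18, 18 and 22 of 35 splits gave as many as the real 1897, 1519 and 2121 (1518 in the fit without missing values filled by the feature's mean, as these fits had them; highest other 18569, 11899 and 41941, the split by scan day each time; 5437, 5678 and 6372 with the block). Lists past the threshold were as many in 17, 4 and 23 of 35 splits (real 10, 12 and 10; highest other 14, 15 and 21), so chance is not excluded for any of these counts. For the glucocorticoid list at 0.3 and 3 ppb, 7 and 10 of 35 splits gave as small a p (-log10 p of 2.17 and 1.99, highest other 4.06 and 5.34), and chance is not excluded there either. Among the 8 splits that part all pairs of a slide, 1, 3 and 3 had as many genes at an unadjusted p under 0.05 (highest other 961, 1658 and 2802), and 5, 1 and 4 as many lists (highest other 14, 10 and 12).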

How the results depend on the processing

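Normexp on the median signal, quantile normalization with the replicate block, and single scan days were chosen after seeing the data. Under all settings run, 2159 values of named genes kept their direction and stayed short of the threshold; list values stayed as they were in 1071 cases, lost the call in 263 and reversed in 10, of which 6 under other settings and 4 without single arrays. Counts of genes past the threshold moved from 0 under quantile normalization, to 4 (0.3 ppb), 19 (0.3 with 3), 8 (3 with 30) and 13 (all doses), and with the replicate block added to 10, 56, 14 and 34, with 5 lists at 3 ppb. Without a filter 4 lists passed between 0.3 and 3 ppb (7 before), and with the replicate block alone 6 between 0.3 and 30 ppb (10 before); pairing left the counts of genes at 0, and beyond the list calls given beside their lists and these counts, the block changed no other call described. The first scan day alone gave 2 genes at 3 ppb, 2 between 0.3 and 3, 2 between 3 and 30 and 1 over all doses, with 6 lists at 3 ppb and 13 between 3 and 30 ppb. The second gave 1 gene at 0.3 ppb, 1 between 0.3 and 3, 1 between 0.3 and 30 and 1 over all doses, with 6 lists at 0.3 ppb. Normexp on the mean signal and the deposited matrix were not run. Single days have fewer arrays; otherwise the cause was not tested.

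Reversed were ribosomal proteins between 3 and 30 ppb under quantile normalization (0.0071, also with the block) and on the second scan day (-0.0503, where the test against other genes turned), heat shock at 30 ppb on the first day (0.0851, likewise), and cholesterol synthesis (-0.1782) and muscle (-0.3722) at 30 ppb on the second; the cause was not tested. Without single arrays, genes numbered 0 to 1 at 0.3 and 3 ppb, 0 to 2 at 30 ppb, and 0 to 1 between 3 and 30 ppb and over all doses, with 1 or more only without 0 ppb replicate 4 or 30 ppb replicate 3. At an unadjusted p under 0.05 they numbered 1262 to 2473, 1079 to 2108 and 1408 to 3289 at 0.3, 3 and 30 ppb. The ranges were 1329 to 3110 between 0.3 and 3 ppb, 671 to 2862 between 0.3 and 30, 871 to 5843 between 3 and 30, and 943 to 2912 over all doses. Lists numbered 6 to 12 at 0.3 ppb (6 without 0 ppb replicate 3), 5 to 16 at 3 ppb (7, 5, 7 and 6 without 0 ppb replicates 1 and 2 and 3 ppb replicates 3 and 4), and 4 to 13 at 30 ppb (4 and 5 without 30 ppb replicate 1 and 0 ppb replicate 4). They numbered 4 to 12 between 0.3 and 3 ppb (12 without 3 ppb replicate 2 or 0.3 ppb replicate 3, 4 without 3 ppb replicate 3 or replicate 4 of 0.3 or 30 ppb) and 7 to 13 between 3 and 30 ppb (13 and 12 without 30 ppb replicates 1 and 3). Medians ranged from -0.099 to -0.008 (ribosomal proteins, 0.3 ppb), -0.1049 to 0.3946 (muscle, 30 ppb), -0.1842 to 0.41 (muscle, 0.3 with 30 ppb) and -0.0974 to -0.0123 (unfolded protein response, 0.3 with 30 ppb). Reversed without single arrays were muscle at 30 ppb and at 0.3 with 30 ppb (without 30 ppb replicate 1) and, by the test against other genes with medians still below 0, ribosomal proteins at 0.3 ppb (without 0 ppb replicate 3) and the unfolded protein response at 0.3 with 30 ppb (without 0.3 ppb replicate 3). Spike-in signal over background, per the file headers, was 13.7 to 23.6 on the first scan day and 63.0 to 119 on the second. A smaller share of spots was well above background on the second, which limits dim probes there.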

Other observations

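Some genes varied widely between brains of the same dose; they were chosen after their values were seen. Against a median residual SD, with dose and slide removed, of 0.189 over 12249 genes (95th percentile 0.567), the immune gene mhc1uba had one of 3.04, the growth hormone gene gh1 2.59, the lysozyme gene lyz 1.81, the metallothionein gene mt2 1.61 and the keratin gene krt91 1.52. The muscle genes pvalb2 and pvalb3 had residual SDs of 1.42 and 1.38. The oxytocin gene oxt, a product of hypothalamic neurons, had a residual SD of 2.04. Its level was 0.95, 4.52, 3.71 and 6.79 in the 4 unexposed brains and 7.03, 6.21, 5.34 and 6.21 after 30 ppb. After 0.3 ppb it was 1.39, 2.03, 4.88 and 6.27, and after 3 ppb it ran from -0.22 to 4.04. Levels of avp, of the related vasopressin, ran from 1.66 to 3.83 without atrazine, from 1.90 to 3.63 after 0.3 ppb, from 0.16 to 2.25 after 3 ppb and from 2.97 to 3.74 after 30 ppb.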
